A study of Mus musculus with 2 samples.

How the data were processed

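The samples were neural stem and progenitor cells (NSPCs) that had been derived from mouse embryonic stem cells through embryoid bodies and grown as floating neurospheres. Both were tertiary neurospheres at passage 2, collected on day 18 counted from the embryoid bodies, per the labels. The control array held total RNA of cells labelled as the control for overexpression, and the miR-153 array held total RNA of cells overexpressing the microRNA miR-153. There was 1 array in each of the 2 groups. Per the labels' protocols, cyanine-3 labelled RNA was made from a low input of total RNA and hybridised to 1-colour Agilent oligonucleotide arrays. Both arrays lay on the same slide, per the file headers, so slide and group were not confounded, and position on the slide differed between them.

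The values used were scanner intensities that the authors deposited, as extracted with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, the processed signal is a background-subtracted intensity on a linear scale, and each spot carries flags for outliers, for saturation and for being well above background. The series table also holds intensity values processed by the authors. Comparison with the scanner values showed that each of its columns equals the processed signal divided by a constant, 381 for the control array and 485 for the miR-153 array. Those columns are therefore linear, not centred and not inverted, with medians of 0.0662 and 0.0614. They were matched by feature number and used only as an alternative source of values. Columns of other samples in that table numbered 0.

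The main values were log2 of the processed signal minus the 75th percentile of that array over non-control spots. Each array had 62976 spots, of which 59305 were not controls. Spots with an outlier flag on either array were left out (229 spots), repeat spots of a probe were averaged, and 55674 probes remained. Probe accessions were matched without versions to a RefSeq gene table of the mouse assembly GRCm38, used for names only. That matched 26296 probes (47.2%), and the other 29378 kept the name in the file. Probe positions are those in the file headers' annotation, on the mouse build mm9 and counted from 1, and no position was converted between builds. Of several probes for a gene, the brightest over both arrays stood for it. This gave 36493 gene names, of which 20456 were well above background on both arrays.

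A gene was counted as higher or lower when it differed at least 2-fold, which is a fixed rule of size and not a test. With 1 array per group there was no test and no p-value. For a gene well above background on a single array the fold is a lower bound. It sets the measured level against the higher of the lowest level of any probe well above background on the other array and the gene's own signal there. That lowest level was -4.34 on the control array and -4.94 on the miR-153 array. A dim gene can therefore be well above background on the miR-153 array only without being higher there. Where the bound is not above 1, no difference is shown. The only technical error in the files was the spread of repeat spots within an array and the spread between different probes of a gene. Precision is limited by the number of arrays, and no spread between cultures could be measured.

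Before the data were examined, 31 gene lists, the alternatives, the 2-fold rule and the rule for named genes were fixed. The lists covered gliogenic transcription factors, markers of astrocytes, oligodendrocytes, neurons, neuronal subtypes and progenitors, proneural and early temporal genes, and JAK-STAT, BMP and Notch signalling. They also covered regional genes along both body axes, cell cycle, pluripotency, synaptic vesicle and microRNA machinery genes, miR-153 targets reported in other systems, 6 stress and response programmes, 7 kinds of other cells, and housekeeping genes. For each list the median difference of the members measured on both arrays was placed among 10000 random lists of the same size. Random lists were drawn with replacement, within 20 bins of mean level, from RefSeq-matched genes and list members. A list stood apart when its median lay outside the central 95% of random lists, which describes these 2 arrays only. Members well above background on a single array enter neither the median nor the counts of higher and lower members.

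Named genes were the 12 most higher and the 12 most lower among genes with a symbol and at least median level. To these came the 4 largest bounds in each direction, up to 4 members per list among those at least 2-fold apart, and 28 genes chosen for the question. Together these were 141 genes. A further 40 genes were named after their values were seen, to account for a count of 5 or fewer or for a feature singled out. Some of the genes so chosen are not reported here.

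The alternatives were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile normalization, scaling on the median of detected probes, lowess on mean level (statsmodels 0.14.6), no filter on dim probes, bright probes only, the mean over probes, the authors' processed values, keeping outlier spots, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. Scaling on the E1A spike-in probes, counting RefSeq-matched genes only, and a search for miR-153 seed matches in the probes were added after the files had been seen. The planned search of 3′ UTRs needed a genome annotation, which was not used here. Other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

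The steps were tested on simulated data built on the 13252 RefSeq-matched genes of this comparison. Of 200 genes given a fold of 1.5, 0 passed the 2-fold rule. All 200 passed at a fold of 2.5 and all 200 at a fold of 4, and 0 unchanged genes did so at each size. The only noise in these folds was the repeat-spot SD, 0.070 on the control array and 0.065 on the miR-153 array. That is small against the distance to the threshold, so this outcome was nearly fixed in advance. Spread between probes of a gene (SD 0.46) and between cultures was left out, so the rate of false or missed calls is not known. For lists of 20 genes, a shift of 0 put 4 of 100 lists outside the central 95%. A log2 shift of 0.5 put 68 of 100 there, and a shift of 1 put 100 of 100 there. These lists were drawn at random after differences had been shuffled among genes of like level. Members of a real list may vary together, so these rates need not hold for the real lists.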

Results

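Gene expression was measured in neurospheres of NSPCs made from mouse embryonic stem cells, with 1 array of control cells and 1 array of cells overexpressing miR-153. NSPCs first make neurons and later gain the ability to make astrocytes and oligodendrocytes, and miR-153 has been studied as a microRNA that acts on this switch through the transcription factors NFIA and NFIB. Of 59305 non-control spots, 31132 (52.5%) were well above background on the control array and 32969 (55.6%) on the miR-153 array. The 75th percentile of signal was 435 intensity units on the control array and 549 on the miR-153 array, against a median background of 42 and 41.5. No spot was saturated. The design has no replicates, so no difference below has a replicate check. Mature miR-153 was not measured by these probes.

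On the miR-153 array, neuronal and oligodendrocyte genes were higher, and genes of the cell cycle and of the response to low oxygen were lower. Among 20456 genes measured on both arrays, 1895 (9.26%) were at least 2-fold higher on the miR-153 array and 2264 (11.1%) at least 2-fold lower. Among the 13252 of them matched to RefSeq genes, 1475 were higher and 1308 lower. The median difference, always given as log2 of the miR-153 array minus the control array, was -0.11 over all genes. Across genes, which are not independent replicates, the levels of both arrays had a Pearson r of 0.954. A further 1953 genes were well above background only on the miR-153 array, 380 of them with a bound of at least 2-fold, and 737 only on the control array, 543 of them with such a bound.

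These sizes compare with a median SD of 0.097 for the difference between single spots of a repeated probe, over 249 probes. Different probes of a gene differed by more, with an SD of 0.46 over 3445 genes with RefSeq-matched probes. The 2 brightest probes had the same sign in 75.3% of those genes, and in 91.1% of the 587 whose brightest probe passed the 2-fold rule. Scaling on spike-in RNA in place of the 75th percentile added 0.23 to every log2 difference and put the median of all genes at 0.13. It gave 2793 genes higher and 1562 lower, so that 64.1% of the genes past 2-fold were higher, against 45.6% in the main setting. Differences below are relative to the 75th percentile, and a sign that turns under another scaling is named where it occurs.

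Among genes of at least median level, the most higher on the miR-153 array was Celf3, a neuronal RNA-binding protein gene, at 20.3-fold (log2 difference 4.34). It was followed by Tal1 (4.02), which encodes a transcription factor of blood and of some inhibitory neurons, Asic4 (3.93), an ion channel gene, and Insm1 (3.74), a gene of newly formed neurons. Lhx5 (3.56), Dlx2 (3.40), Fosb (3.38), Nkain4 (3.30), Id4 (3.21), Slc14a2 (3.20) and Bmp4 (3.15) were also among the 12 most higher. The most lower was Slc16a3, a lactate exporter gene, at 34.3-fold (-5.10). Car3 (-4.42), Lgals1 (-4.37), P4ha2 (-3.96) and Ier3 (-3.81) came next, and the 12 most lower also held Chst7 (-3.60), Slc29a1 (-3.53), Cck (-3.39), Eif4ebp1 (-3.34), Akap12 (-3.33) and Mthfd1l (-3.33). Genes well above background only on the control array were led by Mgarp, at least 93.3-fold higher there, Dhh (at least 35.6-fold), Anxa3 (at least 26.6-fold) and Spp1 (at least 19.4-fold). Only on the miR-153 array, the largest bounds were those of Orly (at least 20.5-fold), St18 (at least 15.3-fold), Sly (at least 11.6-fold) and Spag6l (at least 11.3-fold).

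**Figure D1:**
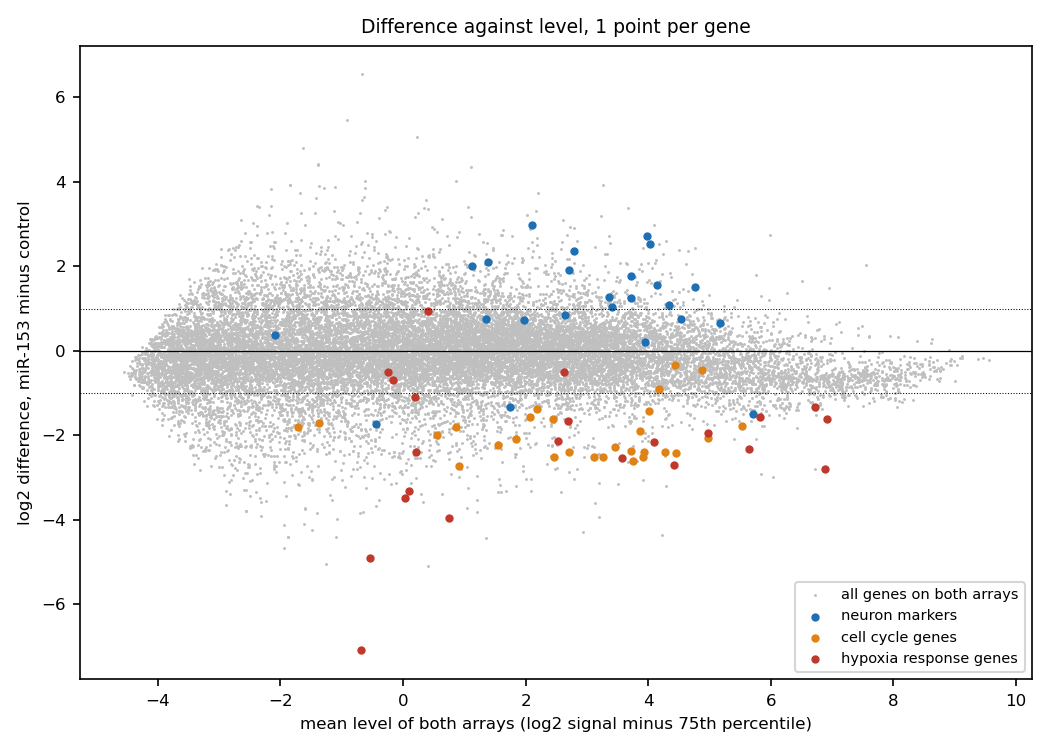
Each point is a gene measured on both arrays, with the mean level of both arrays (log2 signal minus the 75th percentile) on the x axis and the log2 difference, miR-153 minus control, on the y axis; dotted lines mark a 2-fold difference. Neuron markers (blue) lie mostly above 0, while cell cycle genes (orange, median -2.07) and hypoxia response genes (red, median -2.15) lie mostly below it.

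The first question was whether the nuclear factor I genes, which drive the start of gliogenesis, differed. Of the 4 family members, 3 were lower on the miR-153 array and Nfix was higher, a division that held under every scaling tried. Nfia was 2.72-fold lower (-1.44) on a probe at chromosome 4, 97781622 to 97781681, and its other probe gave -1.80. Nfib was 1.84-fold lower (-0.88) on chromosome 4, 81941988 to 81942047, short of the 2-fold rule, and its 5 probes ranged from -1.24 to -0.77. Nfic was 4.16-fold lower (-2.06) on chromosome 10, 80863698 to 80863757, with 3 probes between -2.06 and -1.30. Nfix was 1.26-fold higher (0.33) on chromosome 8, 87250416 to 87250475, and its other probe gave 0.37. All these positions are on mm9, and each of the 12 probes was well above background on both arrays. Every one of these differences exceeded the repeat-spot SD, and those of Nfix did not exceed the SD between probes of a gene.

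Other gliogenic transcription factors went both ways. Of the 20 on the list, 4 were at least 2-fold higher, 2 (Nfia and Nfic) lower and 14 between, with a median of 0.31. That lay inside the central 95% of random lists, -0.34 to 0.37. The 4 higher were Id4 (3.21), Hes5 (2.44), Nr2f2 (1.15) and Id3 (1.02), where the Id and Hes genes encode repressors of neurogenic factors. Hes1, also on the list, was at -0.82. Sox9 was at 0.77, Nr2f1, a factor tied to the timing of the neuron-to-glia switch, at 0.48, and Zbtb20 at 0.03.

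**Figure D2:**
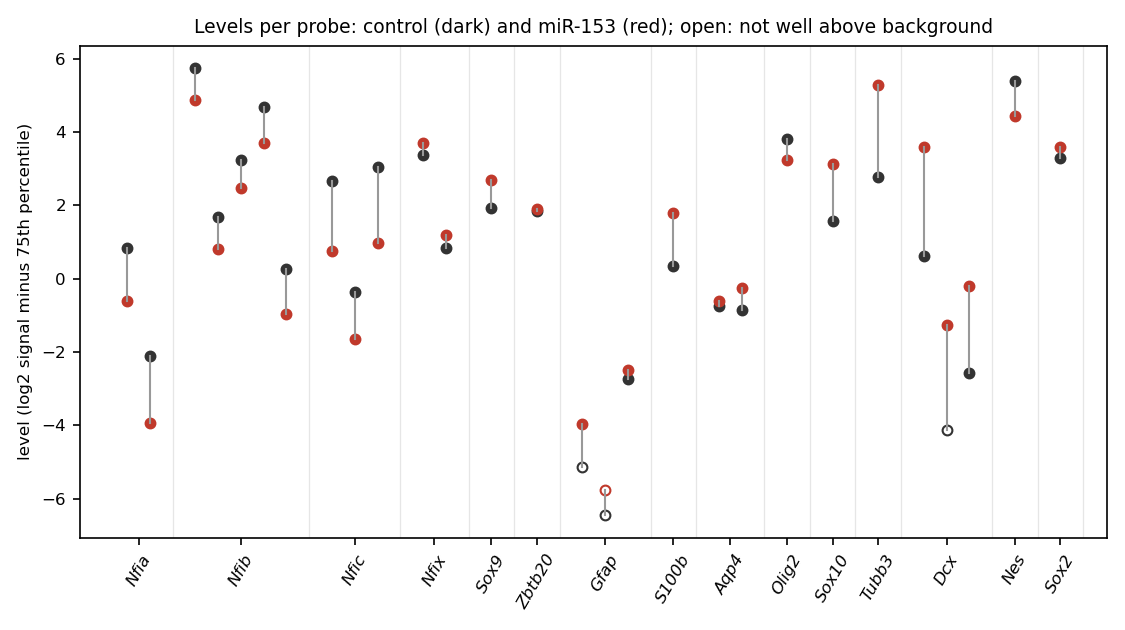
Level of each probe (y axis, log2 signal minus the 75th percentile) of genes chosen for the question, on the control array (dark) and the miR-153 array (red); open circles were not well above background. All probes of Nfia, Nfib and Nfic are lower on the miR-153 array, while those of Nfix, Tubb3 and Dcx are higher.

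Astrocyte markers went both ways. Of 24 measured, 4 were higher, 4 lower and 16 between, with a median of 0.24 inside the random range of -0.37 to 0.31. With bright probes only, the median was 0.60, outside the random range at percentile 99.9. Clu (1.83), S100b (1.44), Id3 (1.02) and Apoe (1.02) were higher. Slc4a4 (-2.51), Tnc (-2.14), Hepacam (-1.55, or -0.78 with normexp) and Cd44 (-1.32) were lower. Gfap, the intermediate filament of astrocytes, was dim on both arrays and differed by 0.23, or by -0.02 with normexp background correction. Its other probes were not well above background on the control array. On the miR-153 array one of those was well above background (difference 1.17), and the other was not (0.70). Aqp4 differed by 0.61, with a second probe at 0.13, and Slc1a3 by -0.15, which turned to 0.08 under spike-in scaling.

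Oligodendrocyte lineage markers were higher as a group, with 10 of 18 measured at least 2-fold higher, 1 lower and 7 between. Their median of 1.19 lay above all 10000 random lists. Genes of myelin were among them, with Cnp 7.36-fold higher (2.88), Mag 5.91-fold (2.56) and Bcas1 5.82-fold (2.54). Sox10, which specifies the lineage, was 2.91-fold higher (1.54). The lower member was Cspg4 (4.01-fold lower), a marker of oligodendrocyte precursors, and Olig2 was at -0.57. Enpp6, Myrf and Opalin were well above background on the miR-153 array only, with Enpp6 at least 2.52-fold higher. The bound of Opalin was 1.02-fold and Myrf had no bound above 1, so both were too dim to show a difference.

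Neuronal genes were higher on the miR-153 array at several stages. Of 24 neuron markers, 14 were at least 2-fold higher, 3 lower and 7 between, with a median of 1.17, above all 10000 random lists. Dcx, of migrating young neurons, was 7.83-fold higher (2.97), with a second probe at 2.37. Nsg2 (2.72), Tubb3 (2.52) and Ina (2.36) followed. The 3 lower members were Nefm (-1.74), Gap43 (-1.50) and Nefl (-1.32), which encode axonal filaments and a growth cone protein. Of 17 proneural and neuronal commitment factors, 8 were higher, 0 lower and 9 between, with a median of 0.99 above all random lists. Insm1 was 13.4-fold higher, Eomes 4.65-fold (2.22), Mfng 4.62-fold (2.21) and Myt1 3.90-fold (1.96), with Eomes at 1.01 and Myt1 at 1.14 under normexp. Neurog2 was well above background on the miR-153 array only, at least 1.49-fold higher.

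Neuronal subtype markers had the highest list median, 1.79, again above all random lists. Of 18 measured, 14 were higher, 0 lower and 4 between, and another 5 (Slc17a7, Isl1, Npy, Calb2 and Reln) were well above background on the miR-153 array only, with Isl1 at least 5.43-fold higher. Slc17a7 and Npy were dim there and had no bound above 1. Gata2 was 27.9-fold higher (4.80), Lhx1 20.9-fold (4.38), Lhx5 11.8-fold (3.56) and Dlx2 10.5-fold (3.40), where normexp background correction put Gata2 at 3.15 and Lhx1 at 2.95. These factors mark several classes of interneurons and forebrain GABAergic cells. Among 29 genes of synaptic vesicle exocytosis, 10 were higher, 1 lower and 18 between, and the median of 0.41 lay at percentile 98.9 of random lists. Syt4 was 5.82-fold higher (2.54, or 1.72 with normexp), Sv2a 2.75-fold (1.46) and Syt5 2.83-fold, and Sv2c was at 1.63.

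**Figure D3:**
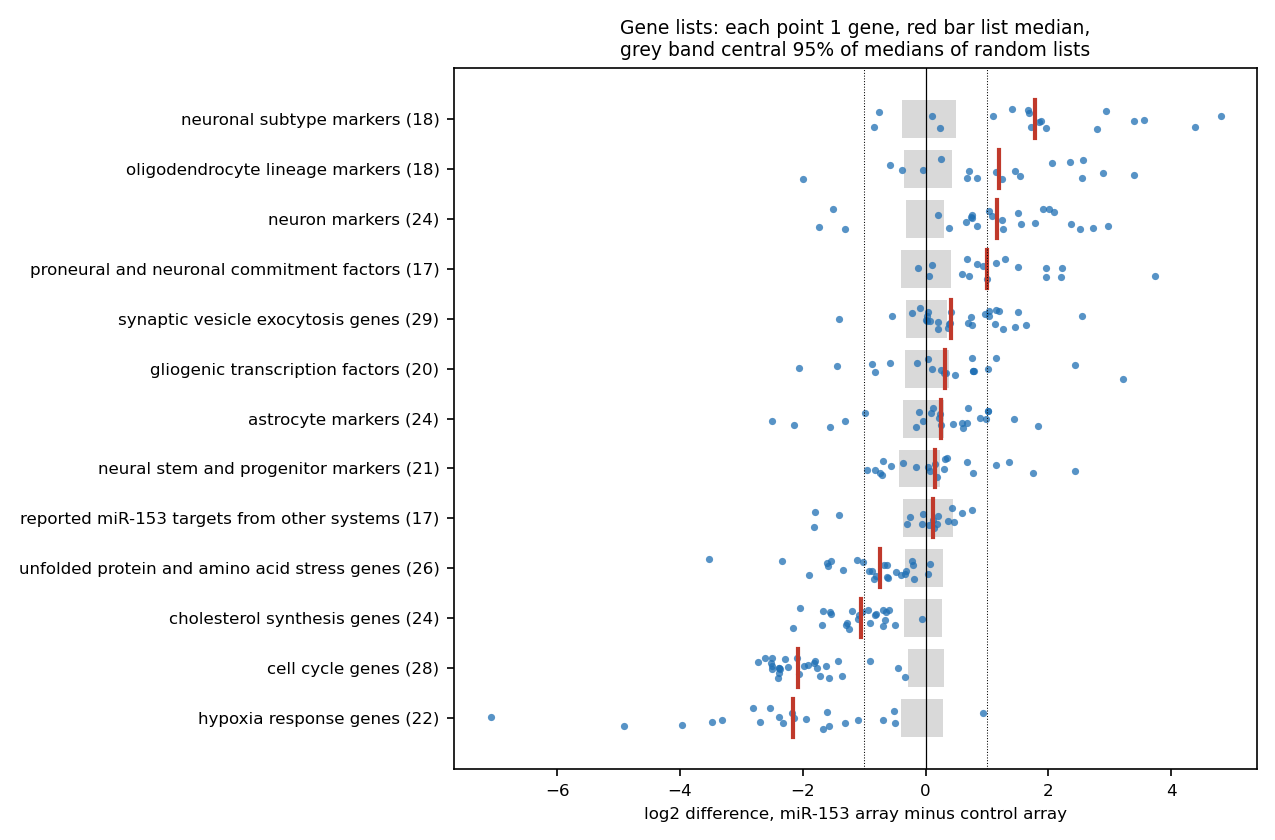
Log2 difference, miR-153 minus control (x axis), of each member measured on both arrays (points) for 13 gene lists, with the number of members in brackets. Red bars are list medians, from 1.79 for neuronal subtype markers to -2.15 for hypoxia response genes, grey bands the central 95% of medians of random lists, and dotted lines a 2-fold difference.

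Progenitor markers differed less than the neuronal ones. Of 21, 4 were higher, 0 lower and 17 between, with a median of 0.15 inside the random range of -0.44 to 0.24, or 0.31 at percentile 99.3 with bright probes only. Hes5, a target of Notch, was 5.41-fold higher (2.44), followed by Prom1 (1.74), Zic1 (1.37) and Sox1 (1.15, or 0.77 as the mean of its probes). Nes, the filament gene used to identify these cells, was at -0.95 and Sox2 at 0.29. Of 21 Notch pathway genes, 3 were higher, 1 lower and 17 between, with a median of 0.45 at percentile 98.6. The higher members were Hes5, Mfng and Nrarp (1.19), and the lower was the ligand gene Jag1 (-1.05, or -0.82 under spike-in scaling). The other Hes and Hey genes on the list did not share the rise of Hes5. Hes1 was at -0.82 and Hey1 at 0.11, and the dim genes Heyl and Hey2 were at -0.51 and 0.76. JAK-STAT and BMP components, which carry astrocyte-inducing signals, had 7 of 26 higher, 2 lower and 17 between, and their median of 0.31 lay inside the random range. Bmp4 was 8.90-fold higher and Socs3, which limits JAK-STAT signalling, 6.40-fold (2.68), while Bmp7 (-1.41) and Bmpr2 (-1.08, or -0.85 under spike-in scaling) were lower. The 2 measured probes of Cntfr disagreed, at 1.46 and -1.34, with a mean of 0.06.

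Genes of the cell cycle were lower almost throughout. Of 28 measured, 25 were at least 2-fold lower, 0 higher and 3 between, and the median of -2.07 lay below all 10000 random lists. Bub1, a mitotic checkpoint kinase gene, was 6.63-fold lower (-2.73). Ccnd1, the cyclin of G1 entry, was 6.13-fold lower (-2.62), Ccnb2 5.73-fold (-2.52) and Ccnb1 5.69-fold (-2.51), with 3 probes of Ccnb1 between -2.83 and -2.28. Aurkb was well above background on the control array only, at least 10.8-fold higher there.

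Genes of early temporal identity in neural stem cells went both ways, with 2 of 18 higher, 3 lower and 13 between. Their median of -0.14 lay inside the random range and was 0.09 under spike-in scaling. Ccnd1, Hmga2 (-1.84) and Hmga1 (-1.59) were lower, and Mycn (1.56) and Nr2f2 were higher. A further 2 members were well above background on the miR-153 array only, Crabp1 (at least 4.35-fold higher) and Nr6a1 (at least 2.65-fold). Lin28b was at 0.68. With normexp background correction Hmga2 stood at -1.36. Pluripotency genes had 4 of 12 lower, 0 higher and 8 between, with a median of -0.55 at percentile 2.00, or -0.85 at percentile 7.77 with bright probes only. Another 2 were well above background on the control array only and 1 on the miR-153 array only. The latter, Pou5f1, was not higher there, at -4.47 against -4.18 on the control array. The 4 lower were Esrrb (-2.48), Klf4 (-1.60), Dppa5a (-1.44) and Dnmt3l (-1.16, or -0.60 with normexp).

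Hypoxia response genes were lower as well. Of 22 measured, 18 were at least 2-fold lower, 0 higher and 4 between, and the median of -2.15 lay below all 10000 random lists. Adm, encoding the vessel-dilating peptide adrenomedullin, was 136-fold lower (-7.09) and close to background on the miR-153 array, and was at -5.44 with normexp. Ndrg1 was 30.0-fold lower (-4.91, or -3.85 with normexp), P4ha2, a collagen prolyl hydroxylase gene, 15.6-fold (-3.96), and Hk2, which starts glycolysis, 11.2-fold (-3.49). Housekeeping genes, fixed as a control list, had 5 of 19 lower, 0 higher and 14 between. Their median of -0.41 was inside the random range, -0.52 to 0.17, or at percentile 1.89 of random lists not matched on level. Over the settings it ranged from -0.42 to -0.04, so it never turned above 0 but came close to it. Pgk1 (-1.57), Tfrc (-1.52), Hprt (-1.51) and Gapdh (-1.15) were among the lower, and Pgk1 is also on the hypoxia list. Housekeeping genes were bright, with a median level of 4.78 on the control array and 4.73 on the miR-153 array. The brightest eighth of all genes, which began at a mean level of 4.04, had a median difference of -0.43. Gapdh stood at -0.44 after lowess, and the other Tfrc probes came as near to 0 as -0.41, and the mean over all its probes was -0.82.

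The next question was whether genes reported as miR-153 targets in other systems were lower. Of 17 measured, 3 were at least 2-fold lower, 0 higher and 14 between, and the median of 0.11 lay inside the random range of -0.36 to 0.45, while the mean was -0.14, or 0.09 under spike-in scaling. Tgfbr2 (-1.81) and Nfe2l2 (-1.81) were among the 3. App was at 0.11, Vamp2 at 0.20 and Snap25 at 0.76. Ptprn2, which holds a miR-153 gene in an intron, was at 0.36, and a second probe of it gave 1.20. Ptprn, also chosen for the question, was at 1.14 (0.71 with normexp). Of 14 genes of the microRNA machinery, 1 was higher, Tnrc6c (1.19), 0 were lower and 13 lay between, with a median of 0.10 inside the random range. Ago3, an Argonaute gene, was well above background on the control array only, at least 2.68-fold higher there.

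Both lists of regional identity genes had medians inside their random ranges in the main setting. Along the anterior-posterior axis, 3 of 10 were higher, 0 lower and 7 between, with a median of 0.26, or 0.30 at percentile 99.5 with no filter on dim probes. Another 7, all Hox genes of hindbrain and spinal cord identity, were well above background on the miR-153 array only, among them Hoxb6 (at least 2.37-fold higher) and Hoxb9 (at least 2.30-fold). Hoxb2, Hoxc4 and Hoxc6 had no bound above 1. Otx1 (1.10) and Emx2 (1.05), both of the forebrain, were among the higher, though at 0.74 and 0.75 with normexp, and 13 of the 31 genes on the list were not well above background on either array. Along the dorsal-ventral axis, 7 of 22 were higher, 1 lower and 14 between, with a median of 0.25. Dbx1 (3.40, or 1.75 with normexp), Gsx1 (3.40), Foxa2 (1.44) and Zic1 were among the higher, and Dbx2 (-1.09, or -0.86 under spike-in scaling) was the lower member.

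Markers of other cell types were examined in the same way. Ependymal and choroid plexus markers had 6 of 13 higher, 0 lower and 7 between, with a median of 0.97 at percentile 99.9. Fam183b (2.73), Folr1 (2.34), Dynlrb2 (1.79) and Aqp1 (1.33, or 0.72 with normexp) led them. Another 2 were well above background on the miR-153 array only, and Kcnj13 on the control array only, at least 4.97-fold higher there. Neural crest and Schwann markers had 6 of 12 higher, 2 lower and 4 between, with a median of 1.04 at percentile 99.9, or -0.05 with no filter on dim probes. A further 1 was well above background on the miR-153 array only. Egr2 (4.02, or 3.09 with normexp) and Tfap2b (2.27, or 1.55) were among the higher, and Pmp22 (-2.20, with a second probe at -0.44 and a mean of -1.32) and Ets1 (-1.65) were lower. Mesenchymal and fibroblast markers had 5 of 21 higher and 5 lower, with a median of 0.06 and a mean of -0.08, or 0.15 under spike-in scaling. Another 1 was well above background on the control array only. Pdgfrb (2.08), Dcn (1.30), Col6a2 (1.27), Col1a1 (1.10) and Lum (1.09) were higher, of which normexp put Pdgfrb at 1.46, Col6a2 at 0.82, Col1a1 at 0.86 and Lum at 0.70. Lower were Fbn1 (-2.92), Fn1 (-1.92), Mgp (-1.78), Loxl1 (-1.54) and Thy1 (-1.26). Few members of the other lists were measured. Of 8 endothelial markers, Flt1 (-2.32, or -1.61 with normexp) was lower and 7 lay between, with a median of -0.57, and another 2 were well above background on the miR-153 array only. Of 6 blood and microglia markers, all lay between (median -0.05, or 0.18 under spike-in scaling, and mean 0.09). Of 6 endoderm markers, Foxa2 was higher and 5 lay between (median 0.32), and another 1 was well above background on the miR-153 array only. Of 5 muscle and cardiac markers, Tnnc2 (-1.66) was lower and 4 lay between (median -0.48), and another 3 were well above background on the control array only and 2 on the miR-153 array only. The medians of these last 5 lists lay inside their random ranges.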

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

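All alternatives were planned except spike-in scaling, the count of RefSeq-matched genes only and the seed search, which were chosen after the data had been seen. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The search of 3′ UTRs and its alternatives were not run. In the main setting, 9 of the 31 lists lay above the central 95% of random lists and 6 below it. Of the 31 lists, 22 stayed on the same side of the central 95% in every setting. Among them were the hypoxia (-2.28 to -1.92), cell cycle (-2.16 to -1.84), neuron (1.06 to 1.40) and oligodendrocyte lists (1.10 to 1.42). With no filter on dim probes the immediate early median turned to -0.048, the neural crest median turned to -0.053, the anterior-posterior median (0.30) moved outside, the seed median was -0.49 at percentile 4.81, and 3641 genes were higher and 4395 lower. With bright probes only, the astrocyte (0.60) and progenitor (0.31) medians moved outside, the pluripotency (-0.85) and p53 (-0.24) medians moved inside, and 721 genes were higher and 910 lower. Quantile normalization moved the interferon median outside (-0.46) and the p53 median inside (-0.29), and lowess moved the immediate early median inside (0.45). Against random lists not matched on level, the interferon (-0.50) and housekeeping (-0.41) medians lay outside. Normexp gave 1204 genes higher and put Hmga2 at -1.36. A threshold of 1.5-fold gave 3806 higher and 5045 lower, 3-fold gave 652 and 878, and RefSeq-matched genes alone gave 1308 lower. These thresholds and filters change the counts by construction, and the cause of the other moves was not tested. Of 156 named genes measured on both arrays, 150 kept their sign in every setting, and normexp moved 24 of them by more than the SD between probes. Signal over background limits the dim genes: the SD of a single-spot difference was 0.156 for dim repeat probes and 0.083 for bright ones.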

Other observations

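In this part, the tests of culture state, of progenitor share and those on the Y chromosome were chosen after the result was seen. The seed search in probe sequences and spike-in scaling were added after the files had been seen.

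Cholesterol synthesis genes were lower on the miR-153 array as a group. Of 24 measured, 13 were at least 2-fold lower, 0 higher and 11 between, and the median of -1.05 lay below all 10000 random lists. Insig1 (-2.16) and Stard4 (-2.04) were the lowest, and the enzyme gene Fdps was at -1.67. Of 26 genes of the unfolded protein and amino acid stress responses, 9 were lower, 0 higher and 17 between, with a median of -0.75 below all random lists. A further member, Slc7a11, was well above background on the miR-153 array only, at least 5.18-fold higher there. Trib3 (-3.53, or -2.85 with normexp), Chac1 (-2.35), Mthfd2 (-1.89) and Cebpb (-1.61) led them. Of 20 p53 response genes, 4 were lower, Gdf15 (13.9-fold), Cdkn1a (3.99-fold), Tnfrsf10b (3.72-fold) and Bbc3 (2.59-fold), with Gdf15 at a log2 difference of -2.29 under normexp, and Btg2 (1.51) was higher. Their median was -0.38 at percentile 1.28, a place the list lost under quantile normalization (percentile 2.58) and with bright probes only (11.4).

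Immediate early genes parted in opposite directions. Of 20 measured, 9 were higher, 4 lower and 7 between, with a median of 0.49 at percentile 98.7, or percentile 97.2 after lowess and -0.05 with no filter on dim probes. Egr2 was 16.2-fold higher (4.02) and Fosb 10.4-fold (3.38), while Ier3 (-3.81), Fosl2 (-2.99, or -2.31 with normexp), Atf3 (-2.86) and Klf4 (-1.60) were lower. Of 14 interferon response genes, Bst2 (2.78-fold), B2m (2.40-fold) and Ddx58 (2.01-fold, or a log2 difference of -0.77 under spike-in scaling) were lower, 0 were higher and 11 lay between, with a median of -0.50 at percentile 3.60, or 2.41 with quantile normalization. Another 3 were well above background on the miR-153 array only and 1 on the control array only. Of 2355 measured transcripts named only by a genomic or intergenic RNA region, 239 were lower and 120 higher, with a median of -0.23. Spike-in scaling turned this balance to 162 lower and 187 higher. Over all genes measured on both arrays, 11.1% were lower and 9.26% higher in the main setting. The dimmest eighth of all genes also had a median of -0.23, and a role of signal level in these transcripts was not tested. Medians over genes of each of the 19 autosomes and the X chromosome lay between -0.06 and 0.07, while 3 copies against 2 would differ by 0.58. Over all probes that carry the name of a RefSeq-matched gene, 9 genes had probes 2-fold apart in opposite directions, Cntfr among them.

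A hypothesis was that transcripts with a miR-153 seed match are lower on the miR-153 array, and it was tested on the 60-base probe sequences, since 3′ UTRs were not used here. Among 13075 genes, the 48 whose probe holds CTATGCA had a median of -0.42, at percentile 1.98 of 606 other words of the same bases. Of these 48, 9 were at least 2-fold lower and 4 higher. The shorter TATGCA (188 genes, -0.14) lay at percentile 1.68, while TATGCAA (52 genes, -0.20) and CTATGCAA (16 genes, -0.32) lay at 7.58 and 9.14. Spike-in scaling, which adds 0.23 to every gene, turns the medians of TATGCA and TATGCAA above 0 and moves the other words alike. The reverse complements, searched as a comparison, lay between 12.8 and 77.0. In the other 9 settings the percentile of CTATGCA was between 0.33 and 2.15, and with no filter on dim probes it was 4.81. The 0.33 came from a comparison with words held by a like number of genes. Scalings that add a constant to every difference cannot change a percentile, so they are no separate check. The hypothesis predicted a median of CTATGCA below the central 95% of its comparison words, and it lay there, as did that of TATGCA. Every probe with CTATGCA also holds TATGCA, so these 2 of the 4 words are not separate results. The longest match, CTATGCAA, lay inside its central 95% and had a median nearer to 0 than CTATGCA. The central 95% of medians of the other words compared with CTATGCA ran from -0.37 to 0.34. A probe covers 60 bases of a transcript, so sites outside it were not seen.

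The low hypoxia response genes argue against array scaling, since their median was -1.92 in the scaling that brought it nearest to 0. A bias that depends on brightness is also argued against, since the median was -1.97 after lowess, and bright spike-in probes differed from dimmer ones by -0.04. The state of the cultures (oxygen, sphere size or medium) may account for the pattern as well as miR-153 could. With 1 array per group these cannot be told apart.

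The low cell cycle genes likewise stayed at -1.84 in the scaling that brought them nearest to 0, and at -2.06 after lowess. The progenitor markers did not fall as far: their median lay 2.22 above that of the cell cycle genes, beyond the SD of 0.90 over those markers. By any amount, 13 progenitor markers were higher and 8 lower, with Nes (-0.95) among the lower. Some, such as Sox9, Hes5 and Slc1a3, are also on the gliogenic or astrocyte lists. Their median therefore does not measure the share of progenitors, and a lower share as the cause was not decided. Slower division of the cells may be a candidate explanation, and it was not tested here.

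Probes placed by the files on the unplaced Y sequence of mm9 appeared on the miR-153 array. Of 112 such probes not well above background on the control array, 54 (48.2%, exact 95% interval 38.7 to 57.9) were well above it on the miR-153 array, against 2963 of 26863 elsewhere (11.0%, interval reaching up to 11.4), which argues against more sensitive detection alone. The interval covers counting error only, and the probes share repeated sequence, so they are not independent. Bounds of the 54 ran from 20.5-fold for an Orly probe down to 0.79, so the dimmest of them show no difference in level. A missing whole Y chromosome in the control cells is argued against by Ddx3y, Eif2s3y, Uty and Ube1y1, which were measured on both arrays with a median difference of 0.33 (SD 0.25). Their probes lie between positions 180154 and 598274 of Y on mm9, so a loss confined to another part of Y was not tested. Local activation of the repeated Y region, or an insertion near it in the cells used for miR-153, may remain, and with 1 array per group it cannot be told apart from an effect of miR-153.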
